A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

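RNA was measured in diploid budding yeast of the BY4743 background, a laboratory strain in common use, in 3 strains: wild type (WT), a strain with ATG1 deleted (atg1) and a strain with ATG41, also called ICY2, deleted (atg41). Per the labels, cultures grown with ample zinc were washed 3 times and held in zinc-limiting medium for 8 h at 30 °C, RNA was extracted with hot phenol, and poly-A RNA selected from 1 µg of total RNA was made into TruSeq libraries for single-end Illumina sequencing. Each strain had 4 libraries, 12 in all. The labels do not say that the 4 libraries of a strain came from separate cultures, so the p-values measure the spread between these samples, which may be partly technical. The kit does not mark strand, so overlapping and antisense genes share reads.

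The deposited count table holds the authors' expected counts per gene, a unit read from its values. The tools named by the submitters' processing notes are BWA, STAR, RSEM and edgeR, with no role given. Tool versions, the genome build and the annotation used by the authors are not given in the sources used here. The authors' deposited comparison tables hold a log2 fold change, a mean log2 CPM, a likelihood ratio score, a p-value and a false discovery rate for each gene in each of the 3 strain pairs. The sign of these log2 fold changes in the authors' deposited tables was read from the deleted genes, and it was turned so that positive means higher in the first strain named. A further 12 columns of per-sample values in the count table match no sample described here and were not used here.

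The table has 6660 features, of which none lacked a gene identifier, and 18.4% of the expected counts used were not whole. They were rounded to whole numbers. Totals ranged from 9623157 to 11247182 expected counts per library, and the number of features with a count from 6415 to 6462. The 10 most abundant genes took 15.2% to 18.7% of the counts. Genes with enough counts (edgeR filterByExpr, minimum count 10, minimum total 15) numbered 6195, of which 457 had no match in the RefSeq annotation of assembly R64. Coordinates are those of R64, 1-based. Reads of near-identical genes, such as ribosomal protein pairs, subtelomeric families and Ty elements, can be split between copies by the authors' counting, so values of single members are uncertain.

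Libraries were scaled with TMM factors and tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test (robust fit, strain as the only factor, all 12 libraries in 1 fit). Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 6195 genes, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. The common biological coefficient of variation was 9.37%. Levels are CPM (counts scaled by library total and TMM factor), given as mean ± SD. Log2 fold changes are given ± SE, and n is 4 libraries per strain for both. With a deleted gene at 0 counts in every library, the fold is a lower bound from a floor of 3 counts per library. With 1 count, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

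Of 40 gene lists fixed in advance, the 37 with at least 5 measured members were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation of 0.01, two-sided) and adjusted over the lists. The deleted gene was left out of a list where it was deleted. The list of genes of the mitochondrial genome had 0 measured members and was not analysed here, and the lists of a-specific and alpha-specific genes had 4 measured members each and were described but not tested. Each call was repeated with an estimated correlation, and fry was run as a further test. Counts of changed members are given over all genes and, where they differ, adjusted over the list alone. GO terms of the RefSeq annotation with at least 10 genes tested, leaving out the largest terms, 574 terms over 5376 annotated genes tested, were tested for an excess of calls with a one-sided hypergeometric test. Values of a single p refer to edgeR for genes and camera for lists unless another test is named.

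The genes named follow a rule. They are ATG1, ATG41 and the zinc readouts ZRT1, ZAP1, ZRT3, ZPS1 and ADH4, and the genes beside ATG1 and ATG41. They include the 6 largest rises and the 6 largest falls among changed genes with a mean log2 CPM of at least 3 whose 4 libraries of one strain all lay above the 4 of the other. They include the 3 largest changes in each of the 6 lists with the highest share of changed members, among lists with at least 3 of these, and the 6 genes in each direction that changed most in both deletions. Other list members are given as examples, and these were chosen after their values were seen. The samples, the tests, the lists, this rule and the alternatives below were fixed before the data were examined, except for those said to be chosen after seeing the data.

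The alternatives were DESeq2 size factors, no filter or a mean of at least 10 counts, the replicate number as a block, each library left out in turn, a fit of only the 2 strains compared, DESeq2 1.42.0, limma-voom, an edgeR exact test, an adjusted p under 0.01, a change of at least 2-fold, an estimated correlation, fry, and a split of the WT libraries. A scaling to equal totals, and a correction that removed from each library its trend of log2 CPM with A content, GC content and coding length, were chosen after seeing the data. Coding sequence was found for 92.6% of the genes tested. The steps were tested on simulated data with 200 changed genes among 6169, and a further list of 20 genes raised by 0.5 on the log2 scale. In the simulation of atg1 against WT, 83.6% of the genes changed by 0.5 on the log2 scale, 94.0% of those changed by 1 and 98.5% of those changed by 2 were recovered, and 4.29% of the calls were false. For atg41 against WT these values were 83.6%, 95.5% and 100%, with 5.61% false, and for atg41 against atg1 they were 79.1%, 95.5% and 98.5%, with 5.24% false. All simulated libraries were drawn from the WT profile, without an outlying library or a composition trend. In the data 65.9% of genes changed in atg41 against WT, so these rates may not carry over. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.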

Results

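Messenger RNA was measured in 12 libraries of zinc-deficient diploid yeast, 4 each of the wild type (WT), of a strain without ATG1 and of a strain without ATG41. ATG1 encodes the protein kinase that starts autophagy, the delivery of cytoplasm to the vacuole for breakdown, and ATG41 encodes a protein needed for full autophagy. The design asks which transcripts differ when either gene is missing during 8 h of zinc deficiency. Libraries held 9623157 to 11247182 expected counts, and 6195 genes were tested. The first principal component of log2 CPM held 65.8% of the variance and set the 4 atg41 libraries (33.9 to 40.7) apart from the 8 others (-24.1 to -16.0), while the second held 8.25%. Replicate 1 of atg1 stood apart from its group. Counts of it and another atg1 library differed with a chi-square per gene of 33.4 to 55.8, against 3.44 to 9.19 for other pairs of replicates, and no pair of libraries agreed within sampling noise.

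The deleted genes were read first. ATG1 (YGL180W, chromosome VII, 160065 to 162758 on the plus strand in R64) had 93.2, 109, 104 and 101 CPM in the WT libraries and 0 counts in all 4 atg1 libraries, at least 347-fold lower than WT at a floor of 3 counts per library. ATG41 (YPL250C, chromosome XVI, 74309 to 74719 on the minus strand) had 727, 660, 686 and 762 CPM in WT. It had 1 count in atg41 replicate 1 and 0 in the other 3, a ratio of counts of WT to atg41 of 29681 with a 95% counting interval of 5327 to 1172390. ATG41 in atg1 (522, 722, 741 and 831 CPM) did not differ from WT (log2 fold change -0.01 ± 0.12, edgeR adjusted p = 0.970). ATG1 in atg41 (87.4, 77.3, 85.2 and 79.1 CPM) fell by 0.31 ± 0.06 on the log2 scale (edgeR adjusted p = 0.00139).

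Genes beside the deletions were also read. GTS1 and TOS3 flank ATG1, and YAH1 and RPL36B flank ATG41. None of these 4 passed the test in atg1 against WT, with RPL36B at 0.36 ± 0.18 and YAH1 at 0.11 ± 0.07. In atg41 against WT, GTS1 was lower (-0.15 ± 0.05, edgeR adjusted p = 0.0228) and TOS3 higher (0.22 ± 0.07, 0.0190), while YAH1 (-0.07 ± 0.07) and RPL36B (-0.40 ± 0.18, 0.0695) did not pass. The GTS1 call was lost without atg41 replicate 2 (0.0515) or replicate 4 (0.0731), and the TOS3 call without WT replicate 2 (0.0621), WT replicate 3 (0.0634) or atg41 replicate 2 (0.0549), and with libraries scaled to equal totals (0.453). GTS1 also did not pass with DESeq2 size factors (0.0574) or in DESeq2 (0.0601). RPL36B passed without atg1 replicate 1 (2.38e-05) or replicate 3 (0.0440).

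Loss of ATG1 was accompanied by higher transcripts of phosphate uptake and storage genes. PHO84, the high-affinity phosphate transporter, rose from 610 ± 15.8 to 975 ± 49.6 CPM (SD, n = 4), a log2 fold change of 0.68 ± 0.06 (edgeR adjusted p = 1.67e-05). PHO11, a secreted acid phosphatase with a near-identical copy in PHO12, rose by 1.15 ± 0.13 (3.53e-04), and SPL2, which acts on low-affinity phosphate uptake, rose by 0.59 ± 0.08 (0.00261). Of the 19 measured genes of the phosphate regulon, 8 rose and 0 fell, or 11 and 1 adjusted over the list alone, with a median of 0.27. The others were VTC3 (0.44 ± 0.05), VTC4 (0.31 ± 0.05) and VTC1 (0.27 ± 0.05), subunits of the vacuolar polyphosphate polymerase, PHO12 (0.29 ± 0.06) and PHO8 (0.26 ± 0.05), the vacuolar alkaline phosphatase. The list as a whole was higher (camera adjusted p = 4.76e-09, adjusted p = 0.0954 with an estimated correlation, fry 2.67e-04). Of the 10 genes of the GO term polyphosphate metabolic process 5 were called higher, where 0.0353 were expected (hypergeometric adjusted p = 4.45e-08).

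In all, 231 genes passed between atg1 and WT, 24 higher and 207 lower with ATG1 among the lower, and 2 rose and 12 fell at least 2-fold. The 3 largest falls besides ATG1 were neighbours at the right end of chromosome III. ADH7, an alcohol dehydrogenase, fell by 1.88 ± 0.08 on the log2 scale (309070 to 310155, 23.5 ± 0.826 to 6.38 ± 0.0714 CPM, edgeR adjusted p = 2.82e-09). RDS1, a zinc cluster protein (310958 to 313456), and AAD3, a putative aryl-alcohol dehydrogenase (313890 to 314981), each fell by 1.65 ± 0.08. PAU3, next inward, was at -0.52 ± 0.27 and did not pass (0.382). Further falls were RRP14 (-1.29 ± 0.24), a ribosome synthesis factor, EAF7 (-1.26 ± 0.24), a subunit of the NuA4 histone acetyltransferase, MLP1 (-1.14 ± 0.20), a nuclear pore basket protein, and MYO1 (-0.96 ± 0.16), the type II myosin of the cytokinetic ring. With the composition and length trend removed these were at -0.68, -0.67, -0.58 and -0.59, and EAF7 (0.0682) and MLP1 (0.131) lost the call. Other rises were the subtelomeric genes YHL049C (0.71 ± 0.17) and COS8 (0.69 ± 0.05), members of families of similar genes, and YPL142C (0.48 ± 0.11), which has no RefSeq match. The nucleolus held 24 of the lower genes among its 225, against 8.20 expected (hypergeometric adjusted p = 9.24e-04). The term was not tested again with the composition and length trend removed, where only 18 genes in all were called lower.

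The count of 231 moved with single libraries. It was 53 without WT replicate 3, 53 without atg1 replicate 2, 77 without WT replicate 2, 109 without atg1 replicate 4, 130 without WT replicate 4 and 457 without atg1 replicate 3, and it was 317 without atg1 replicate 1. Of the 28 named genes called besides ATG1, 9 kept the call with any 1 library left out, and these were AAD3, ADH7, COS8, MYO1, PHO11, PHO84, RDS1, SPL2 and VTC3. The other 19 lost it at least once, 19 without atg1 replicate 2, 18 each without WT replicate 2 or WT replicate 3, 13 without atg1 replicate 4, 10 without WT replicate 4 and 9 without WT replicate 1. Without atg41 replicates 1, 2, 3 and 4, which enter through the shared spread, 7, 9, 1 and 10 lost it. In a fit of only the 2 strains compared 17 of the 28 lost the call, MYO1 among them. Of the calls, 10.4% were higher, against 33.5% of 379 in DESeq2. After removal of each library's trend with base composition and coding length, chosen after seeing the data, 15 were higher and 18 lower, and of the 28 named genes 16 lost the call and SWI4 turned.

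**Figure D1:**
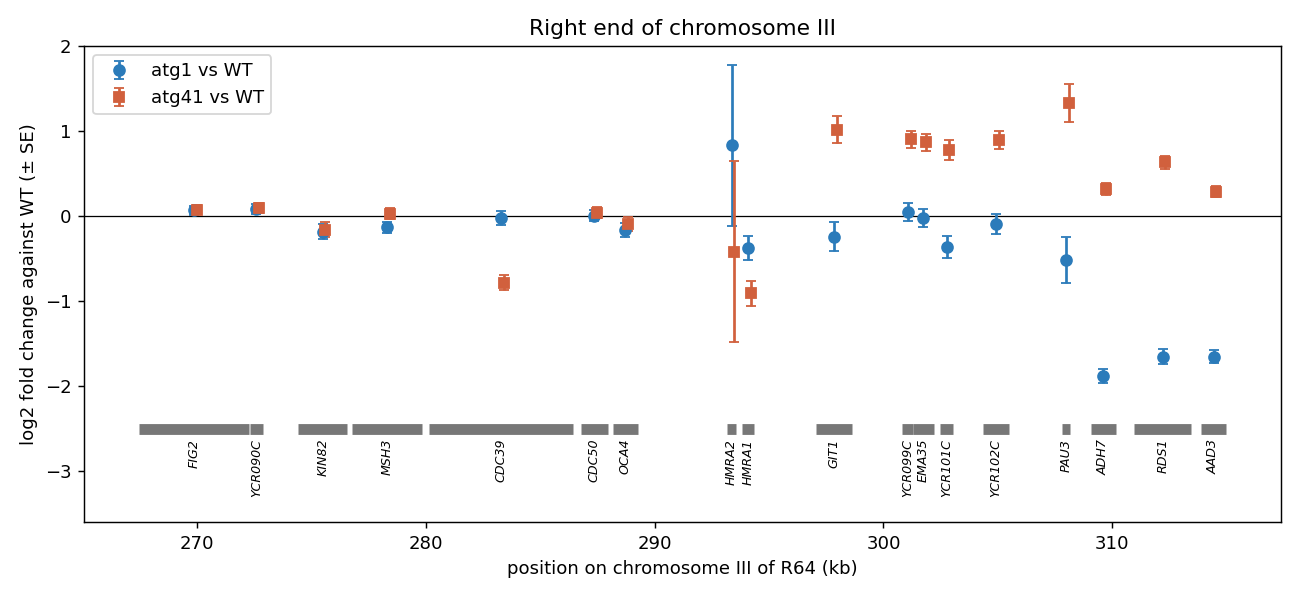
Log2 fold change against WT (± SE, n = 4 libraries per strain) of genes along the right end of chromosome III in R64, for atg1 (circles) and atg41 (squares), with gene bodies as grey bars. ADH7, RDS1 and AAD3 lie at -1.88, -1.65 and -1.65 in atg1 and at 0.32, 0.63 and 0.29 in atg41.

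The zinc readouts did not pass the test in atg1. ZRT1, the high-affinity zinc transporter, was at 15224 ± 434 CPM against 14534 ± 680 in WT (log2 fold change 0.07 ± 0.06), ZAP1, the zinc-responsive activator, at -0.08 ± 0.07, the vacuolar zinc exporter ZRT3 at 0.12 ± 0.06 and ZPS1 at 0.12 ± 0.06. ADH4, an alcohol dehydrogenase induced in low zinc, was at 0.28 ± 0.12 (edgeR adjusted p = 0.185) with replicate 1 at 1710 CPM and the others at 1076 to 1147. Of 24 Zap1 targets 0 rose and 1 fell, RAD27 (-0.34 ± 0.08), with a list median of 0.03 (camera adjusted p = 0.262). With the composition trend removed RAD27 was at -0.24 and lost the call (edgeR adjusted p = 0.132). Among 22 zinc proteins, PHO8 and PMI40 (0.24 ± 0.06) rose and ADH7 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.255), and PHO8 (0.0938) and PMI40 (0.228) lost the call with that trend removed.

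Larger metabolic and ribosomal lists were shifted as sets with few single genes passing. Of 137 ribosomal protein genes 0 passed, with a median of 0.31 (camera adjusted p = 1.17e-13, adjusted p = 0.750 with an estimated correlation), and the median was 0.05 without atg1 replicate 1 (0.00335). Of 19 glycolysis genes 0 passed over all genes and 12 rose adjusted over the list alone, with a median of 0.23 (2.78e-06, adjusted p = 0.716 with an estimated correlation) that was 0.13 without atg1 replicate 1. None of the 24 ergosterol synthesis genes (median 0.11, 1.81e-05) or the 43 Gcn4 amino acid synthesis genes (0.10, 2.66e-04) passed, and each list had adjusted p = 0.716 with an estimated correlation. Both calls were lost with the composition and length trend removed (0.0560 and 0.570). The Gcn4 median was 0.05 without WT replicate 3 and 0.06 without atg1 replicate 4. For these lists edgeR called 0 genes, while unadjusted p-values under 0.05 were found for 1313 genes in all. With an estimated correlation 0 of the 11 lists called by camera kept the call, and fry called 1, the phosphate regulon.

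Core autophagy genes were lower as a list in atg1, with 2 of 19 down, ATG38 (-0.65 ± 0.15) and ATG16 (-0.55 ± 0.13), and a median of -0.11 (camera adjusted p = 0.0176, adjusted p = 0.750 with an estimated correlation). This call was lost without WT replicate 3 (0.0551) or atg1 replicate 1 (median -0.04, 0.140) at equal totals (0.0664) and with the composition and length trend removed (0.185), and the median was -0.18 without atg1 replicate 3 and -0.17 without atg1 replicate 4. Genes expressed in G2/M were lower too, with MYO1 the 1 of 14 that fell, or 4 adjusted over the list alone (median -0.15, 0.0155, adjusted p = 0.716 with an estimated correlation). That call was lost without atg1 replicate 4 (0.0597) and with the composition and length trend removed (0.0891).

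Small upward shifts without a single passing gene were called for zinc transporters (13 genes, median 0.08, camera adjusted p = 0.0448), iron regulon (29 genes, 0.06, 0.0342), TCA cycle (19 genes, 0.08, 0.0278, with 1 rise adjusted over the list alone) and purines (20 genes, 0.06, 0.0176). At equal totals the medians of these 4 lists turned to just below 0, as that scaling put the median of all genes at -0.09. Purines stayed called there (0.0304), and zinc transporters (0.155), the iron regulon (0.128) and the TCA cycle (0.0564) did not. Without WT replicate 3 the adjusted p was 0.177 for zinc transporters (median 0.03), 0.142 for the iron regulon (0.04), 0.0601 for the TCA cycle and 0.0601 for purines (0.03). Without atg1 replicate 4 it was 0.0809, 0.0809 (0.04), 0.0809 (0.05) and 0.0773. Zinc transporters and the iron regulon also lost the call without WT replicate 2 (0.0662 and 0.0578), atg1 replicate 2 (0.0578 and 0.0688) or atg1 replicate 3 (0.0766 and 0.0983), and the median of purines was 0.10 without atg1 replicate 1. With the composition and length trend removed the adjusted p-values were 0.890, 0.698, 0.875 and 0.673. Estimated correlations ended all of these calls, with adjusted p = 0.716 to 0.750 with an estimated correlation.

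The remaining lists were not called in atg1. Ribosome biogenesis had 4 of 57 lower, EBP2 (-0.73 ± 0.15), NOP15 (-0.56 ± 0.14), NOP14 (-0.44 ± 0.10) and BFR2 (-0.42 ± 0.10), or 7 adjusted over the list alone (camera adjusted p = 0.612). In G1/S genes 3 of 20 fell, SMC3 (-0.39 ± 0.10), SWI4 (-0.34 ± 0.08) and RAD27 (list camera adjusted p = 0.667). After removal of the composition trend SMC3 was at -0.10 (edgeR adjusted p = 0.523), SWI4 at 0.03 (0.867) and RAD27 at -0.24 (0.132). With that trend removed EBP2 was at -0.29, NOP15 at -0.05, NOP14 at -0.15 and BFR2 at -0.08, and none of these was called. Meiosis had 2 of 20 lower, ZIP1 and RED1 (-0.35 ± 0.08), which act in meiotic chromosome pairing (0.0576). Single genes passed in the Hsf1 chaperones (BTN2, -0.58 ± 0.11), the proteasome (RPT2, -0.24 ± 0.05), the mitochondrial ribosome (MRPS12, 0.25 ± 0.06) and the vacuolar hydrolases (PHO8), with list p-values of 0.628, 0.684, 0.628 and 0.388. With the composition trend removed ZIP1 (0.0805), RED1 (0.857), BTN2 (0.197), RPT2 (0.162), MRPS12 (0.132) and PHO8 (0.0938) also lost the call. Adjusted over the list alone, Hsf1 chaperones had 1 higher and 1 lower and the mitochondrial ribosome 2 higher and 1 lower. No gene passed in the other tested lists. Their adjusted p-values were 0.169 for selective autophagy, 0.934 for nitrogen catabolite repression, 0.0646 for sulfur and methionine, 0.0543 for oxidative phosphorylation, 0.934 for the retrograde response, 0.636 for hexose transporters, 0.694 for gluconeogenesis and 0.143 for Msn2/Msn4 stress genes. They were 0.195 for the unfolded protein response, 0.117 for Yap1 genes, 0.0534 for phospholipid synthesis, 0.0788 for NAD synthesis, 0.360 for thiamine, 0.483 for histones and 0.483 for daughter cell separation. Haploid-specific genes (0.628) and auxotrophic markers (0.388) also had 0 calls, as did the 4 a-specific and 4 alpha-specific genes.

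**Figure D2:**
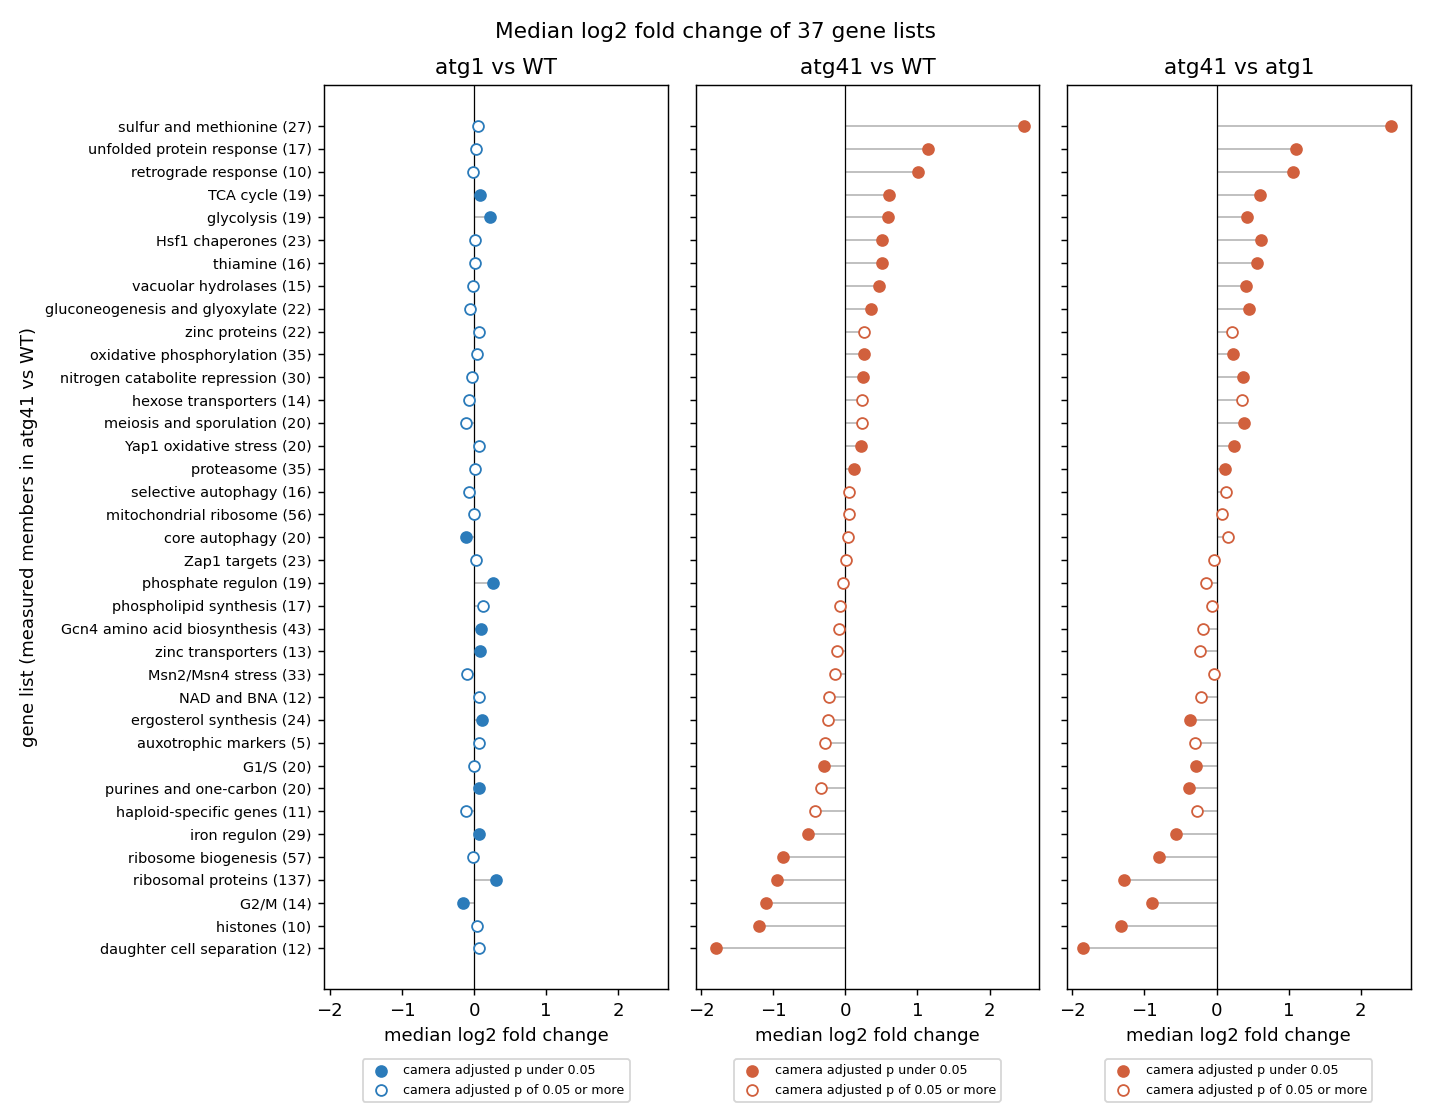
Median log2 fold change of 37 gene lists in each of the 3 comparisons, with filled points for lists with a camera adjusted p under 0.05. Sulfur and methionine genes are the highest list in atg41 against WT at 2.47, and daughter cell separation genes the lowest at -1.79.

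The atg41 strain differed from WT in 4081 genes, 65.9% of those tested, with 1855 higher and 2226 lower, and 251 rose and 419 fell at least 2-fold. Whether each change follows from the loss of ATG41 was not tested. With Ty genes left out, the largest rises named by the rule were mostly in sulfate uptake and assimilation. SUL1, a sulfate transporter, rose from 60.0 ± 1.56 to 2360 ± 260 CPM (log2 fold change 5.30 ± 0.12, edgeR adjusted p = 1.11e-13), MET3, ATP sulfurylase, by 4.86 ± 0.08, SUL2, the second sulfate transporter, by 3.88 ± 0.13, and MET14, adenylylsulfate kinase, by 3.77 ± 0.10. Of 27 sulfur and methionine genes 26 rose and 1 fell, MUP1 (-0.50 ± 0.08), a methionine permease (median 2.47, camera adjusted p = 1.81e-16, adjusted p = 0.0760 with an estimated correlation). MET17 (3.59 ± 0.23) and MET5 (3.51 ± 0.06) were among them. The permease gene AGP3 rose by 4.35 ± 0.10.

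With libraries scaled to equal totals the median log2 fold change of all genes was -0.17 in this comparison, against -0.04 with TMM factors. That scaling gave 1252 higher and 2816 lower, a higher share of 30.8% against 45.5%. The 4081 calls ranged from 3817 to 4347 with any 1 library left out.

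Protein folding genes were also higher in atg41. In the unfolded protein response 16 of 17 genes rose and ERV2 fell (-0.76 ± 0.05), with a median of 1.15 (camera adjusted p = 8.42e-09, adjusted p = 0.0828 with an estimated correlation). ULI1 (3.52 ± 0.11), EUG1 (1.59 ± 0.06), a protein disulfide isomerase, INO1 (1.54 ± 0.11), inositol phosphate synthase, and KAR2 (1.51 ± 0.06), the Hsp70 of the endoplasmic reticulum, were the examples with the largest rises. Of 23 Hsf1 chaperones 19 rose and 1 fell, or 20 and 1 adjusted over the list alone, with HSP60 (1.31 ± 0.07), AHA1 (1.25 ± 0.06) and STI1 (1.25 ± 0.06) up and SSA4 (-1.11 ± 0.13) down. This was the 1 list of 20 that kept its call (median 0.51, 1.55e-06, adjusted p = 0.0113 with an estimated correlation). GO protein folding held 39 of 64 among the higher genes against 20.2 expected (hypergeometric adjusted p = 6.18e-04), COPII vesicle 16 of 22 (0.0123) and the pathway of ER-associated degradation 28 of 49 (0.0204).

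Carbon metabolism genes were mostly higher. TCA cycle genes rose in 16 of 19 and fell in 2, with PYC1 (2.58 ± 0.22), pyruvate carboxylase, CIT1 (1.82 ± 0.06), citrate synthase, and ACO1 (1.43 ± 0.08), aconitase (median 0.60, camera adjusted p = 7.50e-06, adjusted p = 0.0828 with an estimated correlation). The retrograde response, which signals from mitochondria to the nucleus, rose in 8 of 10 and fell in 1, with DLD3 (2.03 ± 0.10) and CIT2 (1.49 ± 0.22) up (1.00, 0.00268, adjusted p = 0.307 with an estimated correlation). CIT1, ACO1, IDH1, IDH2 and PYC1 are in both this list and that of the TCA cycle, so the 2 calls are not independent. Glycolysis rose in 14 of 19 and fell in 2, with PDC6 (3.45 ± 0.21), TDH2 (1.80 ± 0.10) and GLK1 (1.43 ± 0.07) up and ADH1 (-0.35 ± 0.07) down (0.59, 3.38e-05, adjusted p = 0.331 with an estimated correlation). Oxidative phosphorylation rose in 20 of 35 and fell in 3, or 21 and 4 adjusted over the list alone (0.26, 7.71e-05, adjusted p = 0.306 with an estimated correlation). Gluconeogenesis rose in 10 of 22 and fell in 3, with PCK1 (1.49 ± 0.12) up (0.35, 0.0432, adjusted p = 0.691 with an estimated correlation), a call lost without atg41 replicate 2 (0.0506) or replicate 4 (0.0562). Hexose transporters were not called, with 8 higher and 2 lower of 14 (0.198).

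In the list of vacuolar hydrolases 13 of 15 genes rose (median 0.47, camera adjusted p = 5.00e-04, adjusted p = 0.331 with an estimated correlation). Among them were CPS1 (1.95 ± 0.07), PRB1 (1.63 ± 0.17) and PEP4 (0.53 ± 0.06), the carboxypeptidase, protease B and protease A of the vacuole. ATG42 fell (-0.34 ± 0.07). The list also holds the protease inhibitors PBI2 and PAI3 and the neutral trehalase NTH1, so its counts are not of vacuolar hydrolases alone. Thiamine genes rose in 12 of 16 and fell in 1, with THI4 at 1.33 ± 0.29 (0.50, 0.00563, adjusted p = 0.331 with an estimated correlation). Genes under nitrogen catabolite repression rose in 13 of 30 and fell in 6. The ammonium permeases MEP2 (2.56 ± 0.20) and MEP1 (1.69 ± 0.08) rose and the amino acid permease AGP1 fell (-2.14 ± 0.07) (0.25, 0.0284, adjusted p = 0.499 with an estimated correlation). Yap1 genes rose in 11 of 20 and fell in 5, with GSH1 (1.81 ± 0.05), the glutathione synthesis enzyme, up and SOD1 (-1.16 ± 0.20) down (0.22, 0.0226, adjusted p = 0.284 with an estimated correlation). Proteasome genes rose in 17 of 35 and fell in 4 (0.12, 0.0204, adjusted p = 0.284 with an estimated correlation), a direction that turned at equal totals (median -0.02, 0.129). Removal of the composition trend ended the calls of nitrogen catabolite repression (0.358), gluconeogenesis (0.276) and Yap1 genes (0.109).

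Genes of growth and division were lower in atg41. Of 137 ribosomal protein genes 127 fell and 0 rose, or 131 adjusted over the list alone (median -0.95, camera adjusted p = 1.66e-14, adjusted p = 0.497 with an estimated correlation). Of 57 ribosome biogenesis genes 56 fell, with NOP15 at -1.73 ± 0.15 and ENP2 at -1.61 ± 0.15 (-0.86, 1.66e-14, adjusted p = 0.307 with an estimated correlation). In GO terms 195 of 225 nucleolus genes (hypergeometric adjusted p = 1.31e-53) and 75 of 78 of the 90S preribosome (6.45e-27) were lower. All 12 daughter cell separation genes fell, with the cell wall genes SCW11 (-2.35 ± 0.09), DSE1 (-2.15 ± 0.05) and DSE2 (-2.13 ± 0.09) (-1.79, 9.89e-09, adjusted p = 0.0828 with an estimated correlation). All 14 G2/M genes fell, with YRO2 (-2.73 ± 0.05), the transcription factor SWI5 (-1.70 ± 0.11) and the cyclin CLB1 (-1.62 ± 0.10) (-1.10, 7.09e-07, adjusted p = 0.0828 with an estimated correlation). All 10 histone genes fell, with HHF1 (-2.12 ± 0.09), HTA1 (-2.06 ± 0.07) and HHT1 (-2.03 ± 0.08), each with a near-identical copy (-1.20, 2.28e-06, adjusted p = 0.284 with an estimated correlation). In G1/S genes 13 of 20 fell, with PCL1 at -1.70 ± 0.15 (-0.30, 0.0115, adjusted p = 0.445 with an estimated correlation).

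Metal genes moved in both directions in atg41. Iron regulon genes fell in 19 of 29 and rose in 3, or 20 and 3 adjusted over the list alone (median -0.52, camera adjusted p = 6.84e-05, adjusted p = 0.284 with an estimated correlation). The haem oxygenase HMX1 (-1.38 ± 0.07), the cell wall protein FIT1 (-1.37 ± 0.09) and the iron permease FTR1 (-1.35 ± 0.06) fell, and LSO1 (1.78 ± 0.26) rose. ZRT1 fell from 14534 ± 680 to 8263 ± 465 CPM (-0.81 ± 0.06, edgeR adjusted p = 3.30e-08), and ADH4 rose from 1044 ± 19.8 to 3172 ± 104 CPM (1.60 ± 0.12). ZAP1 (0.03 ± 0.07), ZRT3 (-0.12 ± 0.06) and ZPS1 (-0.03 ± 0.06) did not pass, but at equal totals ZRT3 (4.78e-04) and ZPS1 (0.00796) did, and ZRT3 also did without WT replicate 3 (0.0303). Of 23 Zap1 targets 9 rose, such as IZH4 (1.04 ± 0.10), and 9 fell, such as FET4 (-0.96 ± 0.06), a low-affinity metal transporter (median 0.01, 0.916). Zinc transporters rose in 5 and fell in 6 of 13 (0.740), and zinc proteins in 12 and 8 of 22, or 13 and 8 adjusted over the list alone (0.0528).

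Autophagy and other lists had no call. Of 20 core autophagy genes 7 rose and 8 fell, with ATG17 (1.38 ± 0.17), a scaffold of the initiating complex, up and ATG16 (-0.76 ± 0.13) down (median 0.03, camera adjusted p = 0.971). In selective autophagy 3 of 16 genes rose, or 1 adjusted over the list alone, with CUE5 at 0.61 ± 0.06 (0.668). Gcn4 targets split into 15 higher, with SER33 at 3.25 ± 0.07, and 16 lower, with SER3 at -1.66 ± 0.06, both serine synthesis enzymes (0.917). Phosphate regulon genes split into 6 higher and 5 lower of 19 (0.916). PHO84 (-0.86 ± 0.06), SPL2 (-1.07 ± 0.09) and PHM6 (-2.46 ± 0.48) fell, and VTC3 (0.81 ± 0.05) and GIT1 (1.01 ± 0.16) rose. Ergosterol synthesis had 7 higher and 13 lower of 24, with ERG5 (-1.71 ± 0.05) and ERG3 (-1.53 ± 0.08) lowest (0.153). Purines had 6 higher and 12 lower of 20, with HPT1 at -2.11 ± 0.08 and ADE3 at 1.31 ± 0.06 (0.205). The other splits of higher and lower were 6 and 13 of 33 Msn2/Msn4 stress genes (0.413), 5 and 6 of 17 phospholipid genes (0.983), 3 and 6 of 12 NAD genes (0.668) and 20 and 11 of 56 mitochondrial ribosome genes (0.198), the last 20 and 10 adjusted over the list alone.

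Markers of cell type and strain were also read. Haploid-specific genes had 0 higher and 5 lower of 11, with AMN1 at -2.07 ± 0.12 and STE5 at -1.20 ± 0.08 (camera adjusted p = 0.101), and meiosis genes 6 higher and 0 lower of 20, or 5 and 0 adjusted over the list alone, with REC8 at 1.75 ± 0.19 and DMC1 at 0.98 ± 0.10 (0.0734). AMN1 is also in the list of daughter cell separation genes, so its fall counts in both lists. Of 4 a-specific genes STE2 (-0.96 ± 0.13), STE6 (-0.80 ± 0.09) and ASG7 (-1.15 ± 0.29) fell and BAR1 (0.50 ± 0.14) rose, and of 4 alpha-specific genes STE3 (-1.42 ± 0.25) and MF(ALPHA)1 fell and SAG1 (0.29 ± 0.06) rose. STE3 had only 0.648 to 2.01 CPM in the atg41 libraries, and MF(ALPHA)1 only 0.548 to 1.61 CPM in those of atg1, so both rest on low counts. LEU2 and URA3 had 0 counts in all 12 libraries, and of 5 auxotrophic markers 1 rose, MET17, and 3 fell, among them LYS2 (-0.88 ± 0.06) (0.740).

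Large falls outside the lists in atg41 were CHA1 (759 ± 20.2 to 75.7 ± 7.50 CPM, log2 fold change -3.33 ± 0.07), the serine deaminase, PXR1 (-3.03 ± 0.26), a ribosome assembly factor, YLR112W (-2.80 ± 0.19) and DIP5 (-2.69 ± 0.07), a permease for acidic amino acids. Ty genes were also among the largest changes, with YDR316W-B (170 ± 44.2 CPM against 0.451 ± 0.847) and YGR027W-A (0 against 22.8 ± 11.6), and such multicopy elements are uncertain in these counts.

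**Figure D3:**
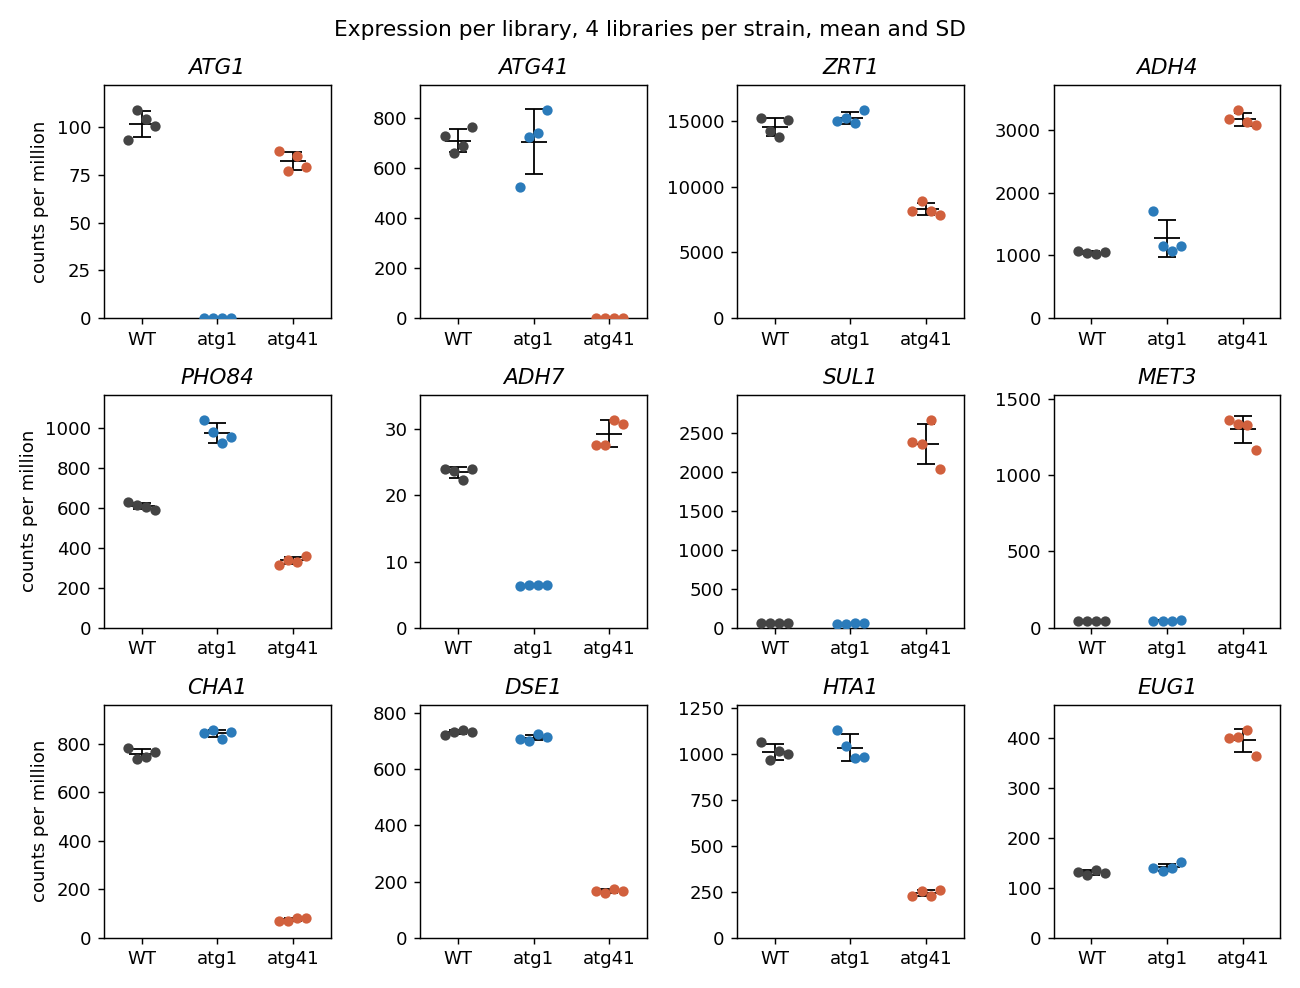
CPM per library of 12 genes, with the mean and SD of 4 libraries per strain. SUL1 lies near 60.0 CPM in WT and at 2360 in atg41, CHA1 at 759 and 75.7, and ADH4 in atg1 replicate 1 at 1710.

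The deletions compared directly differed in 3961 genes, 1918 higher and 2043 lower in atg41 than in atg1, and 284 and 415 of these by at least 2-fold. At equal totals 1556 were higher and 2214 lower, and 3726 to 4049 genes passed with any 1 library left out. SUL1 (5.35 ± 0.12), MET3 (4.81 ± 0.08), AGP3 (4.35 ± 0.10), PDC6 (3.91 ± 0.22) and SUL2 (3.84 ± 0.13) were the largest rises named by the rule with ATG1 and Ty genes left out, and CHA1 (-3.48 ± 0.07) and YLR112W (-2.82 ± 0.19) were among the largest falls. Sulfur and methionine genes were higher in 26 and lower in 1 of 27 (median 2.41, camera adjusted p = 7.18e-16, adjusted p = 0.0895 with an estimated correlation), the unfolded protein response in 16 and 1 of 17 (1.10, 1.96e-08, adjusted p = 0.104 with an estimated correlation) and Hsf1 chaperones in 20 and 1 of 23 (0.61, 1.38e-06, adjusted p = 0.0110 with an estimated correlation). Ribosomal protein genes were lower in 136 and higher in 1 of 137, with the paralogs RPS9A (-2.61 ± 0.17), RPL8A (-2.51 ± 0.23) and RPS22B (-2.09 ± 0.17) lowest (-1.28, 2.23e-21, adjusted p = 0.419 with an estimated correlation). Ribosome biogenesis was lower in 56 of 57 (-0.80, 3.13e-15, adjusted p = 0.307 with an estimated correlation). Daughter cell separation was lower in 12 of 12, with SCW11 (-2.42 ± 0.09), DSE2 (-2.22 ± 0.09) and SUN4 (-2.22 ± 0.09) (-1.86, 2.00e-09, adjusted p = 0.104 with an estimated correlation). Histones were lower in 10 of 10, with HTA1 at -2.09 ± 0.07 (-1.33, 6.21e-07, adjusted p = 0.215 with an estimated correlation), G2/M genes in 13 of 14 (-0.90, 1.57e-06, adjusted p = 0.104 with an estimated correlation) and G1/S genes in 11 of 20 with 1 higher (-0.28, 0.0150, adjusted p = 0.476 with an estimated correlation). In GO terms 182 of 225 nucleolus genes (hypergeometric adjusted p = 8.82e-47) and 14 of 14 of the RNA polymerase I complex (7.71e-06) were lower, and 41 of 64 protein folding genes (1.18e-04) and 26 of 41 of reciprocal meiotic recombination (0.0134) were higher.

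Metabolic lists differed between the deletions too, here as genes higher and lower in atg41, and the second p in each bracket is the adjusted p with an estimated correlation. They were 16 and 2 of 19 for the TCA cycle (camera adjusted p = 3.39e-05, 0.113), 8 and 1 of 10 for the retrograde response (0.00269, 0.307), 13 and 2 of 19 for glycolysis (0.00243, 0.476), 22 and 4 of 35 for oxidative phosphorylation (4.47e-04, 0.321) and 11 and 1 of 15 for vacuolar hydrolases (0.00114, 0.414). Adjusted over the list alone, glycolysis had 13 and 3, oxidative phosphorylation 23 and 4 and vacuolar hydrolases 12 and 1. The list of vacuolar hydrolases also holds PBI2, PAI3 and NTH1. Thiamine genes had 10 and 1 of 16 (0.0143, 0.414), the proteasome 16 and 4 of 35 (0.0156, 0.215), and meiosis 10 and 1 of 20 with REC8 (2.07 ± 0.20), DMC1 (1.00 ± 0.10) and ZIP1 (0.88 ± 0.15) higher (0.00961, 0.215). The iron regulon had 2 and 20 of 29 (3.79e-06, 0.215), and ergosterol synthesis 5 and 13 of 24, or 5 and 14 adjusted over the list alone, with ERG5 at -1.71 ± 0.05 (0.00660, 0.476). Nitrogen catabolite repression had 14 and 6 of 30 (0.0251, 0.476), gluconeogenesis 12 and 4 of 22 (0.0447, 0.620) and Yap1 genes 10 and 5 of 20 (0.0386, 0.307), and all 3 calls were lost without atg1 replicate 1 (0.0557, 0.0972 and 0.0642) and with the composition and length trend removed (0.145, 0.133 and 0.0593). Gluconeogenesis also lost the call without atg41 replicate 2 (0.0528) or replicate 4 (0.0602). Purines had 5 and 13 of 20, with HPT1 at -2.07 ± 0.08 (0.0386, 0.535), a call lost without atg1 replicate 4 (0.0522), atg41 replicate 1 (0.0544) or atg41 replicate 2 (0.0528), and at equal totals (0.0620).

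Lists not called between the deletions gave the following counts of genes higher and lower. These were 8 and 10 for Zap1 targets (camera adjusted p = 0.941), 4 and 7 for zinc transporters, or 5 and 7 adjusted over the list alone (0.297), 12 and 6 for zinc proteins (0.0722), 6 and 3 for core autophagy (0.256), 4 and 1 for selective autophagy, or 3 and 0 adjusted over the list alone (0.206), and 13 and 20 for Gcn4 targets, or 14 and 21 (0.247). The phosphate regulon had 5 and 9 of 19 (0.147), with PHM6 (-3.02 ± 0.45), SPL2 (-1.66 ± 0.09), PHO84 (-1.53 ± 0.06) and PHO11 (-1.16 ± 0.13) lower and GIT1 (1.26 ± 0.16) higher. Hexose transporters had 9 and 2 (0.147), the mitochondrial ribosome 16 and 6 (0.211), Msn2/Msn4 genes 6 and 11 (0.704), phospholipid genes 4 and 8 (0.510), NAD genes 3 and 6 (0.282), haploid-specific genes 0 and 5 (0.101) and auxotrophic markers 1 and 3 (0.420). Of 4 a-specific genes 1 was higher and 3 lower, and of 4 alpha-specific genes MF(ALPHA)1 (-1.67 ± 0.50) and STE3 (-1.58 ± 0.25) were among the 2 lower and MF(ALPHA)2 (0.43 ± 0.15) among the 2 higher. Counts were low for MF(ALPHA)1 (0.548 to 1.61 CPM in atg1) and STE3 (0.648 to 2.01 CPM in atg41). The MF(ALPHA)2 call was lost without atg1 replicate 4 (0.0517) or atg41 replicate 3 (0.0595) and at equal totals (0.0559).

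Zinc readouts and deletion neighbours gave further values between the deletions. ZRT1 was lower in atg41 (-0.88 ± 0.06), as were ZRT3 (-0.24 ± 0.06, edgeR adjusted p = 0.00488) and ZPS1 (-0.15 ± 0.06, 0.0469), while ADH4 was higher (1.32 ± 0.12) and ZAP1 did not pass (0.11 ± 0.07). The ZPS1 call was lost with 8 different libraries left out in turn, with 0.138 the highest value, without atg41 replicate 4. ADH7 was higher (2.20 ± 0.08). GTS1 (-0.16 ± 0.05), TOS3 (0.22 ± 0.08), YAH1 (-0.18 ± 0.07) and RPL36B (-0.76 ± 0.18) passed at 0.0164, 0.0197, 0.0409 and 0.00324. RPL36B was at -0.49 without atg1 replicate 1, and TOS3 at 0.14. The GTS1 call was lost without atg1 replicate 4 (0.0558) or atg41 replicate 4 (0.0551), and that of TOS3 without atg41 replicate 2 (0.0565) and at equal totals (0.154). The YAH1 call was lost without atg1 replicate 2 (0.0848) or 4 (0.106), or atg41 replicate 1 (0.106), 2 (0.0694) or 3 (0.108), in DESeq2 (0.0827) and with the composition and length trend removed (0.0693). The multicopy or subtelomeric YGR027W-A, YGR161C-C, YGR038C-A, YDR545C-A and YDR316W-B were among the largest differences and are uncertain.

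The response to both deletions was compared across genes. Log2 fold changes against WT correlated at r = 0.177 and rho = 0.179 across 6193 genes, which are not independent replicates. Simulated unchanged groups that shared simulated WT libraries gave r = 0.5003 and a covariance of 0.0226, against an observed covariance of 0.0326, a difference of 0.01002. Over the 20 simulations the covariance ran from 0.0111 to 0.0457, so the observed value lay within their spread. With the WT libraries split between the comparisons in 6 ways, r was 0.0652 to 0.146 and the covariance 0.0173 to 0.0349. In both deletions 10 genes were higher (7.19 for independent lists, 2 to 6 with WT split) and 135 lower (74.0, and 1 to 51), and 6 and 14 genes went opposite ways. The simulations gave 0 genes higher and 0 lower in both. They held no changed gene, so that was nearly fixed in advance and is no measure for 10 and 135. With WT split only 10 to 112 genes were called in atg1, so its overlaps are not comparable with 10 and 135. The r was 0.0676 without atg1 replicate 4 and 0.256 without WT replicate 4.

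Genes higher in both deletions were COS8 (0.69 in atg1, 1.02 in atg41), VTC3 (0.44, 0.81), VVS1 (0.37, 1.48), PHO8 (0.26, 0.50), MRPS12 (0.25, 0.25) and the mitochondrial elongation factor gene TUF1 (0.25, 0.58). Genes lower in both were RRP14 (-1.29, -2.34), EAF7 (-1.26, -2.10), the ribosome synthesis gene KRI1 (-1.13, -1.33), SLK19 (-1.04, -1.68), MYO1 (-0.96, -1.53) and BUD22 (-0.96, -0.98). MRPS12 in atg41 did not pass at equal totals (edgeR adjusted p = 0.0839), and BUD22 in atg41 did not pass with the composition trend removed (0.0975). In atg1 that removal also ended the calls of PHO8 (0.0938), MRPS12 (0.132), TUF1 (0.197), EAF7 (0.0682), KRI1 (0.132), SLK19 (0.209) and BUD22 (0.229), and equal totals those of PHO8 (0.0731) and MRPS12 (0.0950).

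The authors' deposited tables were set beside these fits. At a false discovery rate under 0.05, the authors' deposited table for atg1 against WT holds 297 genes, 24 higher and 273 lower, and shares 200 with the 231 called here. Across 6172 genes, which are not independent replicates, log2 fold changes in the authors' deposited table correlated with those here at r = 1.00. The authors' deposited table for atg41 against WT holds 4224, 2051 higher and 2173 lower, and shares 3957. The authors' deposited table for atg41 against atg1 holds 3454, 1644 higher and 1810 lower, and shares 3425.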

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

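Each group of 4 libraries was searched for a library far from the other 3, measured by the gap to its nearest neighbour over the range of the group. Of 337 groups, 17 held such a library, where chance gives about 1 in 20, or 16.9. Their values follow without explanation, and no difference between groups was tested here.

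In mean log2 CPM of gene lists, atg1 replicate 1 was low for the iron regulon (8.98, others 9.13 to 9.15) and atg1 replicate 4 was high for the TCA cycle (7.38, others 7.28 to 7.29). In atg41 replicate 3 ribosomal protein genes were high (7.36, others 7.26 to 7.27), and in WT replicate 3 daughter cell separation genes were low (8.58, others 8.64 to 8.65).

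Single genes are given in CPM. ADH4 was high in atg1 replicate 1 (1710, others 1076 to 1147), EAF7 in WT replicate 3 (51.2, others 39.2 to 41.1), SWI4 in WT replicate 2 (93.1, others 84.9 to 86.1) and STE2 in WT replicate 3 (18.9, others 17.2 to 17.5). PDC6 was high in atg41 replicate 3 (184, others 142 to 148) and low in WT replicate 2 (10.2, others 15.2 to 15.6). MET3 was low in atg41 replicate 4 (1165, others 1330 to 1362), and SLK19 was low in atg41 replicate 3 (8.78, others 16.6 to 17.8). At low counts, MF(ALPHA)1 was low in atg1 replicate 4 (0.548, others 1.47 to 1.61) and STE3 in atg41 replicate 2 (0.648, others 1.79 to 2.01). The multicopy YDR316W-B was high in WT replicate 3 (1.72, others 0 to 0.0849) and atg1 replicate 1 (20.6, others 0 to 0.0914), as was YGR038C-A in atg41 replicate 2 (1.62, others 0 to 0.106).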

How the results depend on the processing

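Equal totals and the removal of the composition and length trend were chosen only after the data were seen. The cause was not tested for any value below unless stated. Genes changed in atg1 against WT numbered 231 and became 378 at equal totals, 33 with the trend removed, 69 with only the 2 strains compared, 379 in DESeq2, 47 at an adjusted p under 0.01 and 14 at 2-fold, the last 2 by construction, and 53 (without WT replicate 3) to 457 (without atg1 replicate 3) with a library left out. At 2-fold, by construction, 670 of 4081 genes remained in atg41 against WT and 699 of 3961 in atg41 against atg1. Lists called in atg1 against WT numbered 11 and became 4 with the trend removed, 0 with an estimated correlation, 1 by fry, and 6 (without WT replicate 3) to 18 (without atg1 replicate 1). With an estimated correlation 1 list was called in atg41 against WT and 1 in atg41 against atg1. By fry 29 and 31 of 37 lists were called in these comparisons, against 20 and 23 by camera. The r of the shared response, 0.177, became 0.241 with no filter on low counts, 0.102 with the trend removed, 0.116 as the mean with WT libraries split, and 0.0676 (without atg1 replicate 4) to 0.256 (without WT replicate 4). The replicate numbers do not pair the libraries (correlations of deviations -0.166 to 0.164, and 4 of 24 best with their own number). With the replicate block 209, 4000 and 3864 genes were called in the 3 comparisons. Directions turned for genes near 0. ATG41 in atg1 turned with DESeq2 size factors (0.00928) and in DESeq2 (0.00981), and ranged from -0.0997 to 0.109 with a library left out. TOS3 in atg1 turned with DESeq2 size factors (0.0195), no filter (1.56e-05), 2 strains (0.00381) and DESeq2 (0.0204), and ranged from -0.0547 to 0.0757. GTS1 in atg1 turned at equal totals (-0.0686) and with the trend removed (-0.0592), and ranged from -0.0212 to 0.0484. ZPS1 in atg41 against WT ranged from -0.0777 to 0.00417. At equal totals ZRT1 in atg1 (-0.0137) and ZAP1 in atg41 (-0.110) turned, and SWI4, called in atg1, was at 0.0346 with the trend removed. Of 798 values of named genes in atg1 against WT, 619 kept direction and call, 162 lost the call and 17 turned; of 1008 in atg41 against WT, 986 kept both, and of 754 in atg41 against atg1, 725. For called lists, 169 of 198, 354 of 360 and 401 of 414 values kept both. An edgeR exact test, limma-voom, DESeq2 size factors, no filter and a mean of at least 10 counts kept the gene counts within 1.5 times of the main ones. At 9623157 to 11247182 counts per library the median SE of a log2 fold change was 0.0793 in atg1 against WT.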

Other observations

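The permease list, the transporters and isozymes named with it, the comparison of residues, the shares without abundant transcripts or the composition trend, and the tests of composition, copy loss, rearrangement, the MET17 marker, scaling and general stress were chosen only after the results were seen. The bounds for composition, atg1 replicate 1, shared reads and sulfur sparing were written after the changed genes were seen, but before the values they test.

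Amino acid permeases were among the genes that fell in atg41. Of 9 permeases under the plasma membrane amino acid sensor Ssy1, 8 fell against WT, with a median of -2.14. The list was put together after falls of its members had been seen, so no test of it as a group is given. Those that fell were DIP5 (-2.69 ± 0.07), GNP1 (-2.56 ± 0.09), BAP3 (-2.51 ± 0.09), TAT1 (-2.16 ± 0.15), AGP1 (-2.14 ± 0.07), BAP2 (-1.21 ± 0.16), TAT2 (-1.20 ± 0.09) and MUP1 (-0.50 ± 0.08), while PTR2 at 0.18 did not pass. Against atg1 the same list had 8 lower (median -2.26). In atg1 against WT edgeR called 0 of the 9 (median 0.14). MUP1 is also in the list of sulfur genes, as is MMP1, and AGP1 is in that of nitrogen catabolite repression. Of transporters picked after their values were seen and not tested as a group, the glutathione and oligopeptide transporter OPT1 rose from 44.0 ± 3.93 to 306 ± 43.7 CPM (2.80 ± 0.10), the S-methylmethionine permease MMP1 by 3.17 ± 0.11 and the low-affinity methionine permease MUP3 by 1.91 ± 0.09.

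Isozymes that differ in sulfur content, picked after their values were seen, gave no single direction in atg41. PDC6, the pyruvate decarboxylase with 6 cysteine and methionine residues of 563, rose by 3.45 ± 0.21 to 154 ± 20.4 CPM, while PDC1, with 17, stayed at a log2 fold change of 0.02 ± 0.07 and did not pass, and PDC5, with 18, fell by 0.44 ± 0.08. ALD6, with 18 residues of 500, fell by 1.86 ± 0.08, and ALD4, with 13 of 519, was at 0.15 ± 0.12 and did not pass (edgeR adjusted p = 0.287). The enolases went the other way, since ENO2 with 11 such residues rose by 1.19 ± 0.10 and ENO1 with 7 by 0.92 ± 0.06. Weighted by transcript level and without ribosomal protein and sulfur genes, cysteine fell most of the 20 residues in the encoded proteins (-6.43%), followed by serine (-4.57%), with methionine seventh (-1.38%).

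Whether other groupings of the libraries give as many genes was tested with all 35 splits of 8 libraries into 4 and 4. For atg1 against WT 1 of 35 splits, the real one, gave 231 genes and the highest other gave 0. For atg41 against WT 1 of 35 gave 4081 and the highest other 0. For atg41 against atg1 1 of 35 gave 3961 and the highest other 1. A share of 1 of 35 is the smallest that these splits can give. Every other split mixed libraries of both strains, so any strain difference added to the spread within its groups. Few calls were therefore likely in those splits, and they cannot decide whether chance gave the 3 counts. Differences between cultures were not tested, since the labels do not say that the libraries of a strain came from separate cultures.

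The lower genes of atg1 formed the first pattern. The 200 with a coding sequence were rich in A (median 38.0% against 32.7% of all genes), and each library's log2 difference from the WT mean correlated with A content, across genes that are not independent replicates, at -0.395 to -0.196 in atg1, -0.198 to 0.294 in WT and -0.228 to -0.157 in atg41. In the other 3 libraries of atg1 than replicate 1 the median difference was -0.45. Those libraries took part in choosing the genes, so that value decides nothing. A refit without atg1 replicate 1 called 285 genes lower, against 207 with all libraries, so the falls do not rest on that library alone. Removing each library's trend took the median from -0.43 to -0.21, or 47.4% of its size, with a median SE of 0.0911 before and 0.0777 after, and 17 of the 200 were still called. A composition bias between libraries may therefore account for much of the fall, and a real fall of A-rich transcripts stays open, while PHO84 (0.62), VTC3 (0.52) and ADH7 (-1.96) stayed called.

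The right end of chromosome III was the second pattern. Among 32 chromosome ends of 4 genes each it was the lowest in atg1 (median -1.65, 3 lower), with the left end of chromosome VI next (-0.52, 2 lower), and at the left end of chromosome VIII 3 genes rose (median 0.49), YHL050C, YHL049C and COS8. For ADH7, RDS1 and AAD3 the log2 fold change nearest to -1 was -1.65. Loss of 1 of the 2 copies, with the other expressed as in WT, is therefore excluded for these genes, which were picked as lying below -1. RNA levels cannot exclude loss of 1 copy together with lower expression of the other. Loss of both copies in every cell is excluded, since the lowest gene kept 65.25 counts per atg1 library. A shift of reads from ADH7 and AAD3 to ADH6, AAD4, AAD6, AAD10 or AAD14 was not seen, since 0 of these 5 genes rose (-0.03 to 0.08). AAD15 and AAD16 were not among the genes tested, so sharing with them stays open. The 5 are alcohol and aryl-alcohol dehydrogenase genes, so this test does not cover RDS1. A rearrangement or silencing of this end in the atg1 strain stays open, since the 0 genes at the WT level beyond ADH7 decide nothing where RDS1 and AAD3, part of the pattern itself, are the only genes there with counts, and whether the change follows from the loss of ATG1 was not tested.

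The sulfur genes of atg41 were the third pattern. Loss of the MET17 marker is excluded, since MET17 had 35244 counts per atg41 library against 3363 in WT, and scaling by abundant genes is excluded, since the list median was at least 2.33 under both other scalings. A general rise of Msn2/Msn4 stress genes is excluded as the whole cause, since 6 of 33 rose and 13 fell. Other kinds of stress response are not excluded, since 19 of 23 Hsf1 chaperones and 16 of 17 unfolded protein response genes rose. A shortage of sulfur amino acids in atg41 is a hypothesis that stays open. The transcript-weighted share of cysteine and methionine outside ribosomal protein and sulfur genes was lower, as sulfur sparing needs (3.10 ± 0.00337% against 3.20 ± 0.00510% in WT and 3.21 ± 0.0105% in atg1, exact permutation p = 0.0286 for atg41 against WT, the smallest that 70 permutations give, 2-sided). This is not particular to sulfur, since 15 of the 20 residues separated all atg41 from all WT libraries, 8 lower and 7 higher, and 5 residues besides cysteine fell more than methionine. Without the 50 most abundant transcripts the share went from 3.25% to 3.21%, and with the composition trend removed from 3.21% to 3.10%.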
